A study of Mus musculus with 6 samples.

How the data were processed

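Total RNA from 6 mouse colorectal tumours was hybridised to 6 Affymetrix whole-transcript arrays, 1 tumour to an array, as biotin-labelled cDNA made with the WT PLUS kit, per the labels' protocols. A whole-transcript array reads each gene with probes spread along its exons and reports 1 value for a probe set. The labels name each sample a biological replicate, and the series' design text gives 3 mice per group. RNA was extracted with an RNAiso kit, inspected on a Bioanalyzer and purified on columns with DNase, per the labels' protocols.

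The deposited values used here were a table of 41345 probe sets in 6 columns, with 0 missing values and 0 columns of other samples. The deposited values were taken as log2 signals, because they ran from 0.973 to 13.6 and the array medians lay between 5.66 and 5.69. Affymetrix Expression Console was used, per the submitters' processing notes; its version, the background correction, the summarisation and the normalization are not given in the sources used here. The deposited log2 values were used on the scale the authors gave them, and whether the arrays had been normalized to each other is left open by those sources. Scanner-level intensities, detection calls, slides and scan dates were not used here, so a low value has no detection call beside it, and batches of arrays were not tested. A normalization that equalises arrays would remove any change shared by most genes.

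Probe sets were paired with genes through the platform's annotation. Of the probe sets, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had none in that table; only those with 1 symbol were named. Entrez identifiers matched the mouse RefSeq table of assembly GRCm38.p6 for 23328 probe sets, and 0 symbols had to be updated. Where a gene had several probe sets, as 1082 genes did, the one with the highest mean over the 6 arrays was kept, which left 22180 genes. Genes with close copies, such as Gapdh and the H2 genes, have probe sets that related transcripts can also bind, and their values are less certain.

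Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on the deposited log2 values, white adipose against non-adipose, with all 6 arrays, no filter on dim genes and no replicate block. Standard errors are limma's moderated ones, and p-values were adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold. The typical standard error of a log2 difference was 0.0972 (median over genes), and the median half-width of its 95% confidence interval was 0.237. The number of arrays limits this precision.

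Gene lists were tested with camera in limma, which asks whether the genes of a list shift together against all other genes, with the preset correlation of 0.01 between the genes of a list, and p-values were adjusted over the 39 lists with at least 5 measured genes. Camera was also run with the correlation estimated from these arrays, and fry was run for the directional p. Of the 40 lists fixed, 1 (red blood cell markers) had only 2 measured genes and was not tested. The lists held 656 different genes, of which 598 had a probe set of their own; symbols that are no longer official were matched through RefSeq synonyms held by a single gene. For each array the mean log2 signal over a list was also taken, and the groups' means were compared by a two-sided exact permutation test, whose smallest possible p for 3 against 3 arrays is 0.1.

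The lists, the design, the rule for naming genes and the alternatives, apart from those marked as added later, were fixed before the data were examined. The rule named the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap. With fewer than 5 such genes it named, in each direction, the 5 genes with the smallest unadjusted p among those changed at least 2-fold, leaving out predicted, clone-based, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor symbols and those sharing a probe set. It also named up to 4 genes with the smallest p from each list past the threshold, up to 2 from other lists, and 10 genes in every case: Cpt1a, Cd36, Fabp4, Adipoq, Vegfa, Slc2a1, Pecam1, Ptprc, Epcam and Mki67. A gene named outside this rule is said to have been chosen after its values were seen.

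The fit was tested on simulated data: in 10 runs, values for the 22180 genes were drawn from each gene's mean and moderated spread, and 200 genes were changed. At 3 against 3 arrays, 98.2% of 4-fold, 89.7% of 2-fold and 33.0% of 1.41-fold changes were recovered, and 5.95% of the calls were false. In the same simulation of independent genes, a list shifted by 0.25 on the log2 scale was called in 10 of 10 runs. Of the unshifted lists, 0.27% were called. The simulated spreads were already moderated, the genes were independent and no array stood apart, so recovery on the real arrays can be lower. For the same reasons the 0.27% does not measure false list calls on the real arrays, whose genes move together within lists. There, a split of the arrays that does not follow the site gave 14 called lists. On the real arrays 31 genes were at least 2-fold higher and 15 at least 2-fold lower, and 0 were called. The absence of calls therefore does not exclude 2-fold changes. Alternatives covered the scaling of the arrays, filters on dim genes, the variance model, array weights, a replicate block, the rule for several probe sets, the threshold, the list test and leaving out each array. The groups share replicate numbers in the labels, which were not treated as pairs.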

Results

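The series compared the gene expression of mouse colorectal tumours grown from cancer cells injected into white adipose tissue, the main fat-storing tissue, with that of tumours from cells injected into non-adipose tissue. Tumours were collected at 1 to 1.5 cm3. There were 3 tumours from each site, each on its own array, and 22180 genes were tested. The arrays were alike in level and correlated across genes at 0.983 to 0.995. The highest correlation was between white adipose replicates 2 and 3, and the lowest was between white adipose replicates 1 and 2. All 3 white adipose arrays correlated less with their own group than with the non-adipose arrays. The mean r was 0.983 against 0.987 for replicate 1, 0.989 against 0.990 for replicate 2 and 0.990 against 0.991 for replicate 3.

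The comparison asked which genes differed between tumours of the 2 sites. The immediate early genes Fosb and Fos, transcription factor genes that respond quickly to stimulation, were lower in the white adipose tumours (3 tumours per site), Fosb 3.04-fold with a log2 difference of -1.61 (SE 0.34) and Fos 2.91-fold with -1.54 (SE 0.47). Rsad2, an interferon-induced antiviral gene, was 2.12-fold lower at -1.08 (SE 0.25), and Slfn4, a myeloid gene of the Schlafen family, 2.16-fold lower at -1.11 (SE 0.36). H2-Eb2, an MHC class II gene, was 2.83-fold higher at 1.50 (SE 0.32), Bmp5, a bone morphogenetic protein, 3.17-fold higher at 1.66 (SE 0.60), and Plce1, a phospholipase C, 2.75-fold higher at 1.46 (SE 0.56). No gene passed the threshold: limma called 0 genes higher and 0 lower at an adjusted p of 0.05, the smallest adjusted p being 0.936. At an unadjusted p under 0.05 there were 368 genes higher and 473 lower, together 841, where 1109 would be passed by chance. This count depended on the arrays. Without white adipose replicate 1 it was 819 higher and 981 lower, and with array weights 728 and 893, each pair together above 1109. Without white adipose replicate 2 it was 298 and 342. Groups did not overlap for 7.31% of the genes, against the 10% that chance gives for 3 against 3 arrays.

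None of the 5 genes named on each side passed the threshold. Fosb averaged 7.84 ± 0.26 (SD, n = 3) on the log2 scale in non-adipose and 6.23 ± 0.67 (SD, n = 3) in white adipose tumours. Acta1, the skeletal muscle actin, differed by -1.26 (SE 0.63), by -1.92 without non-adipose replicate 2 and by -0.66 without non-adipose replicate 3. H2-Eb2 averaged 5.21 ± 0.38 (SD, n = 3) in non-adipose and 6.71 ± 0.57 (SD, n = 3) in white adipose tumours. Aspa, an aspartoacylase, differed by 1.01 (SE 0.36) and the defensin Defb6 by 1.23 (SE 0.55). Defb6 lay at percentile 6.34 of all genes by mean signal, without a detection call, so its lowest values may be background. Defb6 rested on white adipose replicate 1, at 5.08 against 2.92 and 3.19 in replicates 2 and 3 and 2.50 to 2.52 in the non-adipose arrays, and differed by 0.55 without it. The groups of arrays did not overlap for Fosb, Fos, Rsad2, Slfn4, H2-Eb2, Aspa and Defb6, whereas Acta1, Bmp5 and Plce1 overlapped. Bmp5 and Plce1 were high in white adipose replicates 2 and 3 (7.59 and 7.57 for Bmp5, 7.42 and 7.10 for Plce1) and not in replicate 1 (5.49 and 5.26).

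**Figure D1:**
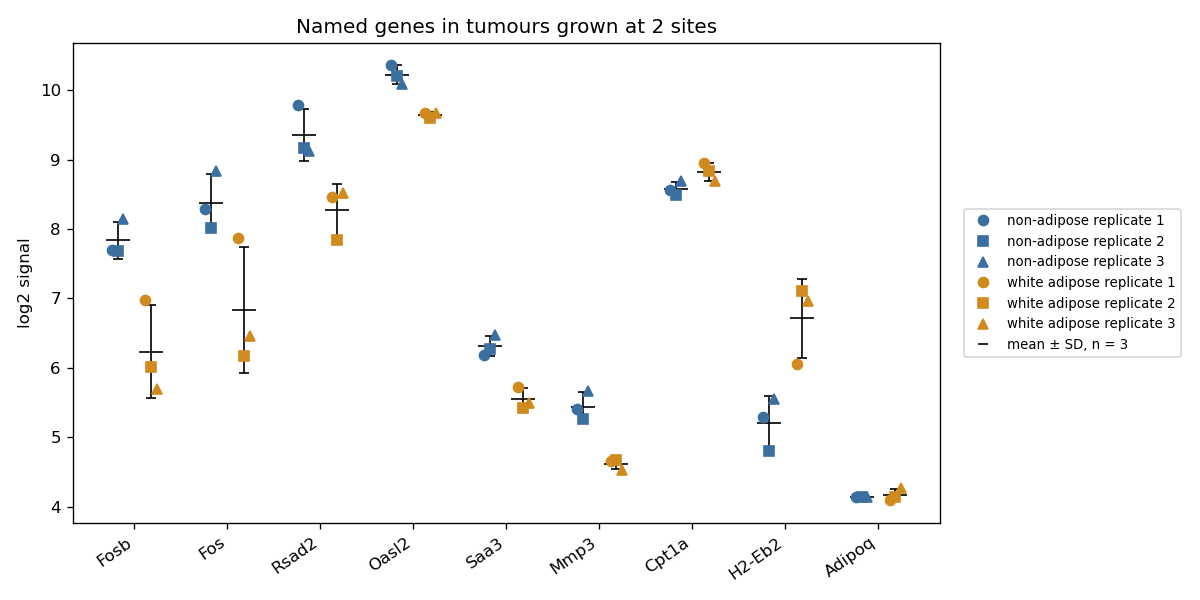
Log2 signal (vertical axis) of 9 named genes (horizontal axis) in each tumour, blue for non-adipose and orange for white adipose, with a symbol for each replicate; bars give the mean ± SD of 3 tumours. Fosb, Fos, Rsad2, Oasl2, Saa3 and Mmp3 were lower and H2-Eb2 was higher in every white adipose tumour, whereas Adipoq lay between 4.10 and 4.27 in all 6.

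Interferon-stimulated genes, the antiviral genes that interferons switch on, were lower as a group in the white adipose tumours. Of the 21 measured, 20 had a lower mean there and 1 a higher mean, and the list averaged 8.82 ± 0.27 (SD, n = 3) in non-adipose and 8.30 ± 0.15 (SD, n = 3) in white adipose tumours, 1.43-fold lower. Oasl2 differed by -0.57 (SE 0.085), Rsad2 by -1.08 (SE 0.25), Oas2 by -0.75 (SE 0.19) and Isg15, a ubiquitin-like modifier, by -0.76 (SE 0.19). The exception was the chemokine Cxcl9, named after its values were seen, at 0.62 (SE 0.55; 0.051 without non-adipose replicate 2 and 0.97 without white adipose replicate 1). None of the 21 passed over all genes tested, 16 were lower at an unadjusted p under 0.05, and 16 passed when adjusted over the list alone. The list fell by camera (adjusted p = 1.96e-18, preset correlation of 0.01). The correlation estimated from these arrays was 0.63, far above the preset, and gave an adjusted p = 0.704. The genes of this list thus moved together, and the counts of lower and of passing genes add little. The array means of the groups did not overlap, with an exact permutation p of 0.1, the smallest this design can give. The call held whichever array was left out, with the mean difference between -0.61 and -0.36.

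Immediate early genes were also lower as a group, 1.45-fold on average. Of 16 measured, 15 had a lower and 1 a higher mean in white adipose tumours. Fosb and Fos led, followed by the phosphatase gene Dusp1 at -0.90 (SE 0.29) and Zfp36, whose protein destabilises mRNAs, at -0.74 (SE 0.25). No member passed over all genes tested, 8 were lower at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. The list averaged 8.13 ± 0.15 (SD, n = 3) in non-adipose and 7.60 ± 0.39 (SD, n = 3) in white adipose tumours; white adipose replicate 1, at 8.04, lay among the non-adipose arrays. By camera the list fell (adjusted p = 3.69e-09), with an adjusted p = 0.704 with an estimated correlation and an exact permutation p of 0.2. The call held whichever array was left out, with the mean difference between -0.75 and -0.38. Skeletal muscle markers were lower in the same comparison, with a mean difference of -0.59.

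Inflammatory cytokine and chemokine genes were 1.17-fold lower on average. Of 23 measured, 18 had a lower and 5 a higher mean in white adipose tumours. Saa3, an acute phase protein gene, differed by -0.76 (SE 0.11), the cytokine gene Lif by -0.40 (SE 0.10), Csf1, the macrophage growth factor, by -0.30 (SE 0.079) and the monocyte chemokine Ccl7 by -0.67 (SE 0.19). None passed over all genes, 6 were lower at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. The list fell by camera (adjusted p = 0.00014), with an adjusted p = 0.74 with an estimated correlation. The mean difference of -0.22 became -0.092 and lost its call without non-adipose replicate 1 (adjusted p = 0.0555), and became -0.38 without non-adipose replicate 2. Neutrophil markers ranked the non-adipose arrays in the same order (5.58, 4.97 and 5.35 in replicates 1, 2 and 3, against 7.035, 6.460 and 6.836 for this list) and differed by 0.038 and -0.27 without replicates 1 and 2. The order does not single out neutrophils. It also held for the hypoxia (9.046, 8.743 and 8.939), interferon-stimulated (9.125, 8.621 and 8.706) and several other lists.

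Genes of fatty acid beta-oxidation, the mitochondrial breakdown of fatty acids, were slightly higher in the white adipose tumours. Of 18 measured, 15 had a higher and 3 a lower mean, and the list averaged 8.06 ± 0.018 (SD, n = 3) in non-adipose and 8.13 ± 0.016 (SD, n = 3) in white adipose tumours, 1.05-fold higher. Cpt1a, the enzyme that admits long-chain fatty acids to mitochondria, differed by 0.24 (SE 0.091). The electron transfer flavoprotein gene Etfb differed by 0.17 (SE 0.071), Etfdh by 0.13 (SE 0.065) and Cpt2 by 0.11 (SE 0.078; 0.046 without white adipose replicate 2). No member passed over all genes or when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. The list rose by camera (adjusted p = 0.0121), with an adjusted p = 0.704 with an estimated correlation. That estimate was -0.015, below the preset, so correlation between its genes does not account for the lost call. The unadjusted camera p was 0.0025 with the preset and 0.031 with the estimate. Array means of the groups did not overlap (exact permutation p = 0.1), and the call was lost without non-adipose replicate 1 (0.068, adjusted p = 0.0625) and without white adipose replicate 2 (0.065, adjusted p = 0.0648).

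Other lipid lists did not pass. Fatty acid uptake and binding genes differed by 0.082 on average over 15 genes (camera adjusted p = 0.386), with 9 higher and 6 lower, and by 0.0085 without non-adipose replicate 2. In that list Acsl4, which activates polyunsaturated fatty acids, was at 0.21 (SE 0.091), the transporter Slc27a1 at 0.35 (SE 0.16) and the fatty acid receptor Cd36 at 0.83 (SE 0.56; 0.39 to 1.36 with 1 array left out). Lipid storage and lipolysis genes differed by 0.055 (adjusted p = 0.167; 0.012 without white adipose replicate 1), with Hilpda, a hypoxia-inducible lipid droplet gene, at -0.28 (SE 0.11) and Bscl2 at 0.28 (SE 0.17). Fatty acid synthesis genes differed by 0.036 (adjusted p = 0.202; 0.022 without white adipose replicate 1 and 0.065 without white adipose replicate 2), with Acss2 at 0.20 (SE 0.08) and Acaca, the acetyl-CoA carboxylase, at -0.13 (SE 0.059). Cholesterol synthesis genes differed by -0.027 (adjusted p = 0.894, and by -0.11 with an adjusted p of 0.0213 without white adipose replicate 1), with Hsd17b7 at 0.21 (SE 0.062) and Nsdhl at -0.19 (SE 0.09). Target genes of the lipid-sensing PPAR receptors had a mean of -0.016 and a median of 0.012 (adjusted p = 0.89, direction up). Peroxisomal oxidation differed by 0.048 (adjusted p = 0.272; 0.0036 without non-adipose replicate 1). The TCA cycle differed by 0.015 (adjusted p = 0.817) and oxidative phosphorylation by 0.013 (adjusted p = 0.406), and with array medians subtracted these became -0.0068 and -0.0081.

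Hypoxia response and glycolysis genes had lower means in the white adipose tumours. For hypoxia, 19 of 23 genes were lower and 4 higher, 1.17-fold on average, with Car9, a carbonic anhydrase, at -0.80 (SE 0.41), Ldha, the lactate dehydrogenase, at -0.34 (SE 0.19), the oxygen-sensing hydroxylase genes Egln1 at -0.20 (SE 0.12) and Egln3 at 0.30 (SE 0.18). For glycolysis, 14 of 17 were lower and 3 higher, 1.12-fold on average, with Pfkl at -0.27 (SE 0.13), Pgam1 at -0.27 (SE 0.15) and Gapdh at -0.096 (SE 0.06). Vegfa, the main endothelial growth factor, differed by -0.016 (SE 0.22; 0.0036 after quantile normalization) and the glucose transporter Slc2a1 by -0.39 (SE 0.36). With 1 array left out Slc2a1 ran from -0.76 to -0.060 and Car9 from -1.18 to -0.40, in both genes weakest without white adipose replicate 2. No gene of either list was at an unadjusted p under 0.05, and none passed over all genes or when adjusted over the list alone. Both lists fell by camera (adjusted p = 0.0133 and 0.00944), each with an adjusted p = 0.74 with an estimated correlation. Without white adipose replicate 2 the differences shrank to -0.034 and -0.063, and without white adipose replicate 1 they grew to -0.43 and -0.26. The calls were lost without white adipose replicate 2 (adjusted p = 0.778 and 0.228), non-adipose replicate 1 (-0.16 with 0.175, and -0.13 with 0.0877) or non-adipose replicate 3 (-0.21 with 0.176, and -0.14 with 0.194).

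Proliferation genes were 1.09-fold lower on average, with 24 of 25 lower, among them the replication genes Mcm3 at -0.15 (SE 0.061), Pcna at -0.25 (SE 0.12) and Mcm2 at -0.17 (SE 0.089), and Ube2c, which acts in mitosis, at -0.35 (SE 0.16). Mki67, the common proliferation marker, differed by -0.059 (SE 0.13). The array means of the proliferation list were 9.36, 9.40 and 9.25 in non-adipose replicates 1 and 2 and white adipose replicate 1. They were 8.96, 8.96 and 9.11 in non-adipose replicate 3 and white adipose replicates 2 and 3. The list thus divided the arrays along a line other than the site. Its genes moved together, with an estimated correlation of 0.81, so the count of lower genes adds little. Of the p53 target and apoptosis genes, 11 of 14 were lower, 1.08-fold on average, with the cell cycle inhibitor Cdkn1a at -0.53 (SE 0.17), Zmat3 at -0.18 (SE 0.08), Ccng1 at -0.19 (SE 0.10) and Aen at -0.11 (SE 0.064). Of the epithelial-mesenchymal transition genes, 11 of 14 were lower, 1.15-fold on average, with the matrix metalloproteinase genes Mmp3 at -0.82 (SE 0.12), Mmp13 at -0.88 (SE 0.54) and Mmp10 at -0.46 (SE 0.31) and the cadherin Cdh2 at -0.35 (SE 0.11); Mmp3 was the 1 member that passed when adjusted over the list alone. Mmp3, Mmp10, Mmp13 and Cdh2 lay at percentiles 30.9, 44.4, 47.4 and 43.8 of all genes by mean signal. No detection call was at hand, so their lowest values may be background. Without non-adipose replicate 1 Mmp13 was at -0.32 and Mmp10 at -0.11. None of these genes passed over all genes, and no proliferation or p53 gene passed when adjusted over the list alone. The 3 lists fell by camera (adjusted p = 0.00128, 0.00688 and 0.0283 in the order given), with an adjusted p = 0.74, 0.704 and 0.74 with an estimated correlation. Proliferation lost its call without non-adipose replicate 1 (-0.071, adjusted p = 0.166), non-adipose replicate 2 (-0.049, 0.227) or white adipose replicate 2 (-0.057, 0.228), and moved from -0.13 to -0.27 without non-adipose replicate 3 and to -0.20 without white adipose replicate 1. The p53 list lost it without non-adipose replicate 1 (-0.089, 0.0625) or white adipose replicate 2 (-0.0065, 0.0796), and moved from -0.11 to -0.17 without non-adipose replicate 2, -0.068 without non-adipose replicate 3, -0.28 without white adipose replicate 1 and -0.046 without white adipose replicate 3. These moves owed much to Perp, named after its values were seen, which is also on the skin epithelial list and stood at 9.57 in white adipose replicate 1 and 8.03 in non-adipose replicate 3. With Perp left out, a check added after the data were seen, the p53 list differed by -0.13 (adjusted p = 0.00385), by -0.19 without white adipose replicate 1, by -0.073 without white adipose replicate 2 (0.0583) and by -0.096 without non-adipose replicate 1 (0.0498). The transition list lost it without non-adipose replicate 1 (-0.14, 0.175) or white adipose replicate 3 (-0.13, 0.364), and with Mmp3 left out, also tried after the data were seen (-0.16, 0.154).

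**Figure D2:**
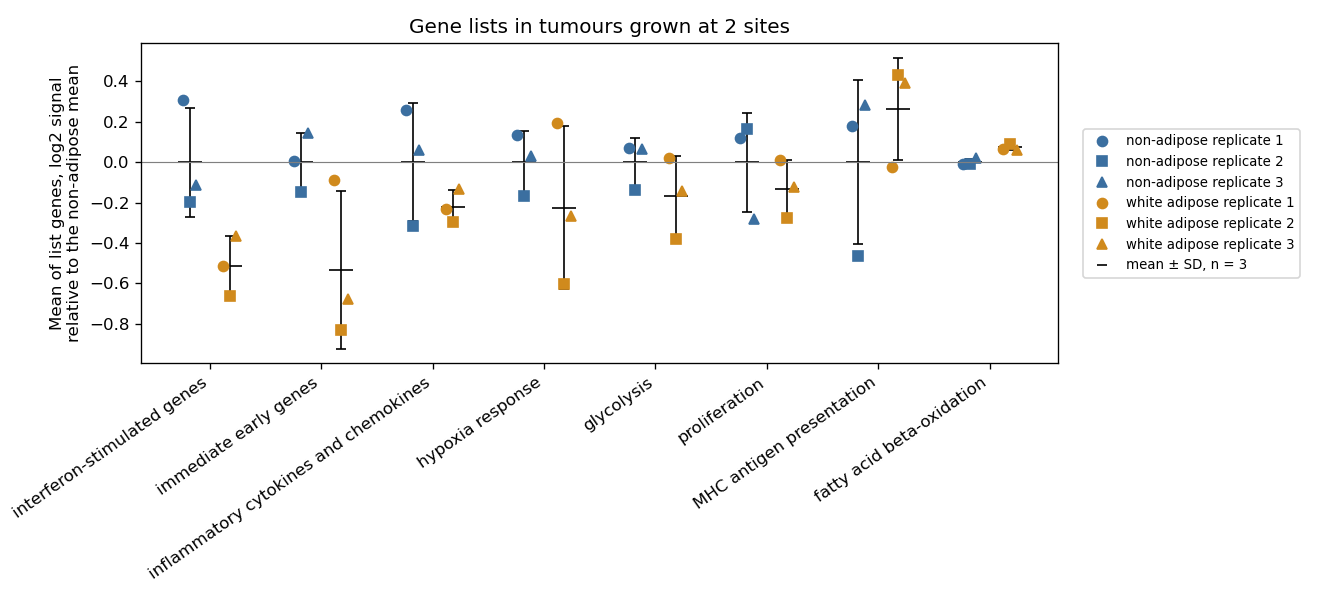
Mean log2 signal of 8 gene lists (horizontal axis) in each tumour, relative to the non-adipose mean of the list (vertical axis, log2), blue for non-adipose and orange for white adipose; bars give the mean ± SD of 3 tumours. The tumour groups were apart for the interferon-stimulated and the fatty acid beta-oxidation lists and overlapped for the other 6.

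Antigen presentation genes of the MHC were 1.20-fold higher on average in the white adipose tumours, with 11 of 14 higher and 3 lower. The class II genes H2-DMb1 at 0.22 (SE 0.077), H2-DMa at 0.61 (SE 0.38), H2-Eb1 at 0.77 (SE 0.54) and H2-Aa at 0.70 (SE 0.49) had the smallest p-values of the list. None passed over all genes or when adjusted over the list alone, and 1 was at an unadjusted p under 0.05. Without non-adipose replicate 2, H2-DMb1 was at 0.17, H2-DMa at 0.27, H2-Eb1 at 0.24 and H2-Aa at 0.20. The list rose by camera (adjusted p = 0.0446), with an adjusted p = 0.755 with an estimated correlation of 0.70. With genes that moved together to this degree, the count of higher genes adds little. Its mean difference of 0.27 became 0.033 without non-adipose replicate 2, where the list was lowest (adjusted p = 0.695), and the call was also lost without white adipose replicate 2 (0.18, 0.244) or 3 (0.20, 0.207). It was 0.41 without white adipose replicate 1 and 0.41 without non-adipose replicate 3. Dendritic cell markers and T and NK cell markers were likewise lowest in non-adipose replicate 2 (8.79 for the MHC list, 6.30 and 5.51) and next lowest in white adipose replicate 1 (9.23, 6.40 and 5.76).

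Markers of other cells in the tumour samples were compared next. Skeletal muscle markers were 1.51-fold lower on average in the white adipose tumours, 16 of 18 lower, with none passing when adjusted over the list alone, and with Ckm, the muscle creatine kinase, at -0.52 (SE 0.18), Casq1 at -0.40 (SE 0.17), Actn3 at -0.93 (SE 0.42) and myoglobin, Mb, at -0.30 (SE 0.14). Non-adipose replicates 3 and 1 were highest for this list (6.89 and 6.39), and non-adipose replicate 2 (5.64) lay below all 3 white adipose arrays (5.67 to 5.77). The list fell by camera (adjusted p = 4.66e-06), with an adjusted p = 0.74 with an estimated correlation; its difference of -0.59 became -0.30 without non-adipose replicate 3 and -0.93 without non-adipose replicate 2. Skin epithelial markers averaged 8.11 in white adipose replicate 1 and 6.62 in non-adipose replicate 3, against 5.36 to 5.63 in the other 4 arrays (camera adjusted p = 0.579; difference -0.51 with an adjusted p of 0.00794 without white adipose replicate 1, against 0.40 over all arrays). With those 2 arrays left out, an alternative added after the data were seen, camera called 4 lists higher and 9 lower and limma again called 0 genes, with 1103 higher and 1242 lower at an unadjusted p under 0.05. The interferon list then differed by -0.57, the immediate early list by -0.68, the beta-oxidation list by 0.088 and the muscle list by -0.33, the last no longer called (adjusted p = 0.0851). Other called lists moved by over 1.5 times: proliferation from -0.13 to -0.34 (adjusted p = 1.01e-12, the smallest), and hypoxia from -0.22 to -0.42. MHC moved from 0.27 to 0.55, p53 from -0.11 to -0.24 and transition from -0.20 to -0.31. The arrays kept were non-adipose replicates 1 and 2 and white adipose replicates 2 and 3. The split of the 6 arrays that gave the most genes (2472 at an unadjusted p under 0.05) parted them the same way. Differences in this alternative therefore cannot be told apart from that split, which does not follow the site.

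Adipocyte markers did not separate the sites. Over 16 genes their mean difference was -0.021 and their median 0.037, and the camera adjusted p was 0.192 (direction up). Without white adipose replicate 2 the mean was 0.079 and the adjusted p 0.03. Adipoq, the adipocyte hormone adiponectin, differed by 0.028 (SE 0.067) and lay at percentile 15.6 of all genes by mean signal. Thrsp was at 0.12 (SE 0.057), and the fatty acid binding protein gene Fabp4 differed by -0.43 (SE 0.55). Endothelial markers had a mean of -0.011 and a median of 0.016 (adjusted p = 0.907, direction up), with Pecam1 at -0.026 (SE 0.14), the tight junction gene Cldn5 at 0.21 (SE 0.074) and the apelin receptor gene Aplnr at -0.36 (SE 0.16). Angiogenic factor genes differed by -0.11 (adjusted p = 0.0784; -0.17 with 0.00794 without white adipose replicate 1, -0.14 with 0.0182 with array weights, and -0.069 without white adipose replicate 2), with the chemokine Cxcl12 at -0.52 (SE 0.14) and Mmp9 at -0.71 (SE 0.20). Macrophage markers had a mean of -0.082 and a median of 0.015 (adjusted p = 0.272, direction down; mean -0.14 without non-adipose replicate 2 and -0.035 without non-adipose replicate 3), with Itgam at -0.22 (SE 0.073) and the scavenger receptor Msr1 at -0.52 (SE 0.23). T and NK cell markers differed by 0.15 (adjusted p = 0.108), by -0.025 without non-adipose replicate 2, and by 0.28 and 0.37 without white adipose replicate 1 and without non-adipose replicate 3, where they passed (adjusted p = 0.0177 and 3.93e-06). They also passed with array medians subtracted (0.13, adjusted p = 0.0471), with array weights (0.24, 0.0107) and without both arrays that held skin genes (0.49, 2.42e-07). Ptprc, carried by all leukocytes, differed by -0.034 (SE 0.24). Intestinal epithelial markers differed by 0.084 (adjusted p = 0.0854; 0.11 with 0.0409 without white adipose replicate 2), with Epcam at 0.082 (SE 0.18). This list had low signals, averaging 5.82 in non-adipose and 5.90 in white adipose tumours. Epcam lay at percentile 29.1 of all genes by mean signal, without a detection call, so its values may be background. Pericyte and smooth muscle markers differed by -0.079 (adjusted p = 0.323; -0.24 with 0.0382 without white adipose replicate 1), with Rgs5 at -0.38 (SE 0.17) and Kcnj8 at -0.29 (SE 0.13). Fibroblast and matrix genes had a mean of 0.065 and a median of -0.024 (adjusted p = 0.762, direction up; mean -0.068 with 0.0213 without white adipose replicate 1), with the proteoglycan Lum at 0.99 (SE 0.42) and Fap at -0.25 (SE 0.11).

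**Figure D3:**
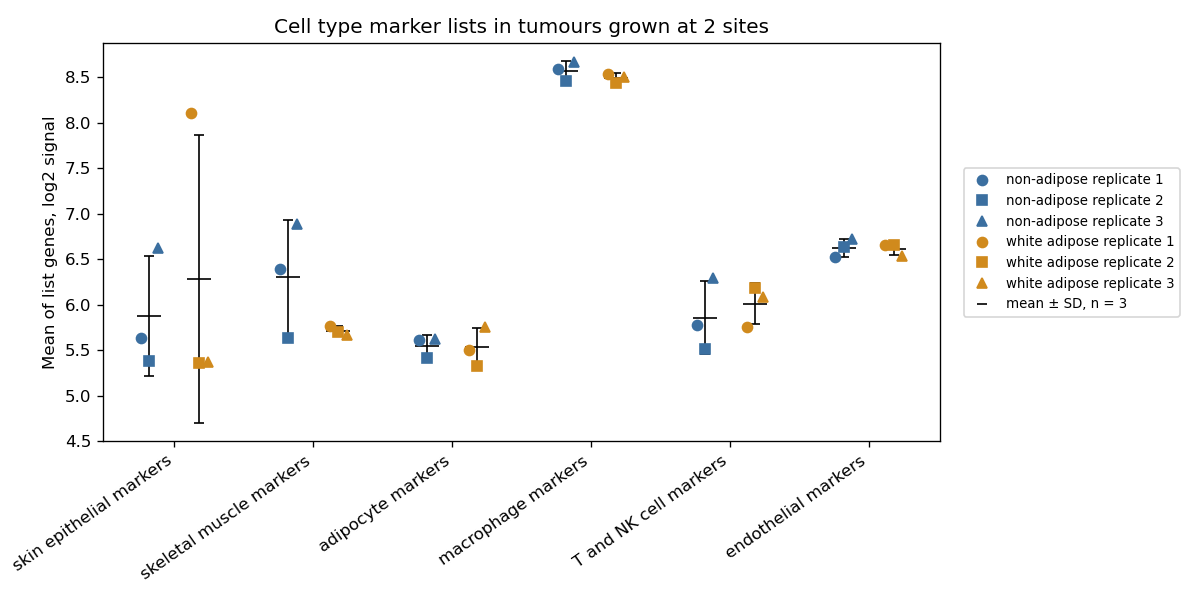
Mean log2 signal (vertical axis) of 6 cell type marker lists (horizontal axis) in each tumour, blue for non-adipose and orange for white adipose; bars give the mean ± SD of 3 tumours. Skin epithelial markers stood highest in white adipose replicate 1 (8.11), and skeletal muscle markers in non-adipose replicates 3 and 1 (6.89 and 6.39).

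In all, camera with the preset correlation of 0.01 called 2 lists higher and 9 lower among 39. It called 0 with the correlation estimated from these arrays, where the smallest adjusted p was 0.704. Among the called lists that estimate ran from -0.015 (beta-oxidation) to 0.81 (proliferation), with 0.63 for interferon-stimulated and 0.55 for immediate early genes. Where it lay far above 0.01, the p-values with the preset correlation are likely too small. By fry, 0 lists passed after adjustment (smallest adjusted p = 0.262) and 3 had an unadjusted p under 0.05, namely interferon-stimulated genes, fatty acid beta-oxidation and Wnt target genes. Wnt targets differed by -0.072 over 14 genes, 7 higher and 7 lower, with the cyclin gene Ccnd1 at -0.24 (SE 0.068) and Myc at -0.33 (SE 0.16), and were not called by camera (adjusted p = 0.427). Over all lists 19 genes passed when adjusted over the list alone, 16 of them interferon-stimulated genes, which moved together and are not independent results. Array means of the groups did not overlap for 3 of the 40 lists (interferon-stimulated, beta-oxidation and Wnt), 7.50%, against the 10% that chance gives. Of the 91 genes followed with each array left out, 44 moved by over 1.5 times or turned sign when some 1 array was left out. So did 34 of the 39 lists. With only the upper 50% of genes by mean signal, the hypoxia, MHC and p53 lists were no longer called (adjusted p = 0.0534 for each) although their differences hardly moved (-0.22, 0.27 and -0.11), and the muscle list was at -0.40 (adjusted p = 0.0661). The transition list kept 9 of its 14 genes, without Mmp3, Mmp10, Mmp13 and Cdh2 among others, and averaged -0.029 (adjusted p = 0.918).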

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

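The alternatives without both arrays that held skin epithelial genes, without Perp and without Mmp3 were chosen after the data were seen; all others were planned. Limma called 0 genes in either direction under every alternative run (scalings, filters, variance trend, array weights, block, mean of probe sets, every probe set, 2-fold minimum, adjusted p of 0.10, each array left out), with the smallest adjusted p between 0.121 and 0.993. A different background correction and a slide or scan block were not run, because only processed values were used and no slide is given. For lists, camera's 2 higher and 9 lower became 1 and 5 with the upper 50% of genes, 3 higher with array medians subtracted, 4 higher and 11 lower with array weights, 1 higher with the replicate block, 4 higher without the skin arrays, and 0 and 0 with an estimated correlation or by fry; leaving out each array gave 1 to 4 higher and 3 to 15 lower. The causes were not tested beyond the fewer genes of the filter. Interferon-stimulated and immediate early lists kept their call in all 15 alternatives with the preset correlation. With the upper 50% of genes, hypoxia (-0.2243), MHC (0.2692), p53 (-0.1147), muscle (-0.3981) and transition (-0.02912) lists lost it (adjusted p = 0.0534, 0.0534, 0.0534, 0.0661 and 0.918); hypoxia, MHC and p53 differences hardly moved. With Mmp3 alone left out the transition list was at -0.156 (0.154), and with Perp left out the p53 list at -0.1272 (0.00385). With the replicate block 0 genes were called in either direction and lists were 1 higher and 11 lower; the MHC list was then at an adjusted p of 0.0635, and NRF2 (0.0394) and angiogenic (0.0482) lists were called, as they were with array weights (0.00723 and 0.0182). The block changed no other call. The labels do not say that the numbers pair the arrays. Deviations from the group means correlated at 0.142, 0.064 and 0.0641 for numbers 1, 2 and 3. Among the arrays of the other site, 4 of 6 arrays correlated best with their own number. A weak pairing is therefore not excluded. With median subtraction the genes at an unadjusted p under 0.05 split 258 higher and 614 lower, against 368 and 473.

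The log2 differences that turned sign belonged to genes and lists that passed no threshold over all 6 arrays. After quantile normalization Vegfa was at 0.003599, and with array medians subtracted the TCA cycle was at -0.00679 and oxidative phosphorylation at -0.008122. PPAR target genes were at 0.03323 with the upper 50% of genes, and with the upper 75% the value was, for brown and beige adipocyte markers 0.06733. With array weights the values were, for Ptprc 0.07262, Perp -0.7972, Krt14 -0.3229, oxidative phosphorylation -0.00017, adipocyte markers 0.0009167, fibroblast and matrix genes -0.0163, mast cell markers -0.1755, skin epithelial markers -0.1301 and mesothelial markers 0.003178. Without both skin arrays the values were, for Fabp4 0.2592, Vegfa 0.03585, Pecam1 0.0561, Ptprc 0.3006, Perp -0.6041, Krt10 -0.1743, Krt14 -0.1343, oxidative phosphorylation -0.02268, adipocyte markers 0.02866, endothelial markers 0.01472, fibroblast and matrix genes -0.04165, B and plasma cell markers 0.06683, mast cell markers -0.4656 and skin epithelial markers -0.1405. Leaving out 1 array at a time also turned signs, and the differences then ran over these ranges, lowest to highest, for Adipoq -0.02315 to 0.0634, Epcam -0.06576 to 0.2729, Fabp4 -1.038 to 0.000525, Krt10 -0.1534 to 2.691, Krt14 -0.846 to 1.057, Mki67 -0.1899 to 0.02085, Pecam1 -0.1389 to 0.0931, Perp -1.438 to 0.9444, Ptprc -0.2583 to 0.1466, Vegfa -0.2151 to 0.147, B and plasma cell markers -0.1602 to 0.01443, PPAR target genes -0.03379 to 0.01795, T and NK cell markers -0.02512 to 0.3686, adipocyte markers -0.1344 to 0.07921, cholesterol synthesis -0.1094 to 0.05002, endothelial markers -0.06287 to 0.03702, fibroblast and matrix genes -0.06819 to 0.1686, mast cell markers -0.3137 to 0.4144, mesothelial markers -0.05113 to 0.08593, neutrophil markers -0.2659 to 0.03837, oxidative phosphorylation -0.006946 to 0.02675, pericyte and smooth muscle markers -0.2391 to 0.008597, skin epithelial markers -0.5127 to 0.8623 and unfolded protein response -0.09481 to 0.03191.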

Other observations

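The tests for leukocytes, for adipocytes and for array splits at the adjusted threshold were chosen after the results were seen, and the other tests were fixed earlier. Some genes with small unadjusted p-values lay outside the naming rule and were chosen after their values were seen. Sfrp2, a secreted Wnt modulator, was 1.40-fold lower in the white adipose tumours (6.28 ± 0.030 against 5.80 ± 0.046, SD, n = 3), the membrane protein gene Lrp11 1.62-fold lower, and Chil3, a chitinase-like gene of myeloid cells, 1.87-fold lower, while Mlph, which tethers melanosomes, was 1.45-fold higher. None passed limma's threshold (adjusted p = 0.936 for each).

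Dendritic cell markers differed by 0.14 on average (camera adjusted p = 0.264; 0.029 without non-adipose replicate 2), lymphatic endothelial markers by 0.13 (0.381), mast cell markers by 0.16 (0.326), neutrophil markers by -0.10 (0.907) and B and plasma cell markers by -0.083 (0.108). NRF2 antioxidant genes differed by -0.10 (0.108; -0.036 without white adipose replicate 3), unfolded protein response genes had a mean of -0.039 and a median of 0.015 (0.946, direction down), brown and beige adipocyte markers a mean of -0.021 (0.954), mesothelial markers a mean of -0.0026 and a median of 0.032 (0.665, direction up), and nerve and Schwann cell markers a mean of -0.031 (0.863). The 2 red blood cell genes averaged 5.21 at both sites, and that list was not tested. T and NK cell markers, called higher in 5 alternatives, spanned a wide range: over all alternatives with the preset correlation their adjusted p ran from 2.42e-07 to 0.995. Without white adipose replicate 1, dendritic cell markers (0.28, adjusted p = 0.0105) and NRF2 genes (-0.23, adjusted p = 0.000656) also passed, and with array weights both passed again (0.23 with 0.0415, and -0.19 with 0.00723). B and plasma cell markers passed without non-adipose replicate 2 (-0.16, adjusted p = 0.0283) or white adipose replicate 2 (-0.11, adjusted p = 0.0409), and NRF2 genes without non-adipose replicate 2 (-0.15, adjusted p = 0.0283).

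Hair follicle and muscle genes, chosen after their values were seen, went together in the non-adipose arrays. Tchh, the hair sheath protein trichohyalin, was at 8.58 in non-adipose replicate 3 and 5.28 in replicate 1, against 2.20 in replicate 2 and 2.22 to 2.50 in the white adipose arrays. The hair sheath keratin Krt71 was at 8.81 and 6.83 in the same arrays and 4.73 in non-adipose replicate 2, and the fast myosin Myh4 at 8.27 and 6.48, against 3.95 in non-adipose replicate 2. Epidermal keratin Krt10 was at 11.6 in white adipose replicate 1 and 5.90 to 6.16 in the other 5 arrays, and Krt14 at 8.54 there and 7.23 in non-adipose replicate 3.

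Interferon-stimulated genes were lower in the white adipose tumours by camera with the preset correlation, and not past the threshold with an estimated one (adjusted p = 0.704) or by fry (0.415). A lower share of macrophages and of T and NK cells alike is argued against. The macrophage list differed by only -0.0824 (-0.14 to -0.035 with 1 array left out), against -0.51 for the interferon list. The T and NK cell list differed by 0.15, by -0.025 without non-adipose replicate 2 and by 0.37 without non-adipose replicate 3. The rule applied, that a lower share would take both lists at least 0.5 times as far, was set after the results. It does not cover a loss of 1 leukocyte type. A single array is argued against as well, since leaving out non-adipose replicate 1, the most influential, kept 70.1% of the difference. The site of growth, a loss of or a shift within 1 leukocyte type and a difference in handling between the sites stay open and were not tested.

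Immediate early genes were lower by the same test, again not with an estimated correlation (adjusted p = 0.704; exact permutation p = 0.2). A single array does not account for it, since 72.0% of the difference remained without white adipose replicate 2, the most influential. More muscle in the non-adipose samples cannot be told apart from the site: with the muscle list as a covariate the difference was -0.372 with a standard error of 0.327, which 6 arrays leave too wide to decide. These genes also respond to dissection and delay before freezing, for which the labels give no times, and that was not tested.

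Fatty acid beta-oxidation genes were slightly higher by camera with the preset correlation, and not past the threshold with an estimated one (adjusted p = 0.704). The estimate was -0.015, below the preset, so correlation between these genes does not account for that loss. The call was also lost without non-adipose replicate 1 (0.0625) or white adipose replicate 2 (0.0648). Adipocytes carried along cannot be told apart from the site: 5 adipocyte markers (Adipoq, Lep, Retn, Plin1 and Cidec) differed by 0.0566 and the list by 0.074, with a standard error of 0.118 for the gap. An earlier form of this test, which set replicate 3 apart, was dropped because that grouping was taken from the values. Leaving out any 1 array kept at least 88.0% of the mean difference, which argues against a single array as its source; the site of growth stays open and was not tested.

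The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 841 genes and the highest other split 2472, with 3 of the 10 splits at least as high. At the adjusted threshold the real split gave 0 genes, which all 10 splits reach by construction (highest other 3), so that count tests nothing. For lists by camera with the preset correlation, the real split gave 11 and the highest other 14, with 5 of the 10 splits at least as high. The split with 2472 genes set non-adipose replicates 1 and 2 and white adipose replicate 1 against the other 3 arrays, which points to a structure of the samples that does not follow the site.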
